A study of Homo sapiens with 6 samples.

How the data were processed

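RNA of 6 cultures of BG02 cells, 3 kept in conditioned medium and 3 kept in 0.2 mM butyrate, was measured on 3 2-colour Agilent whole human genome arrays. Per the file headers, the scanner files were made with Agilent Feature Extraction 9.1 and give spot brightness as intensity, both as mean signal with local background and as a processed signal that the software had background-subtracted and dye-normalized. Per the file headers they also give a log ratio on the log10 scale, red over green, which was not used. The deposited value table of the series holds log2 values. Its scale was found by comparison with the scanner files: each column followed the log2 processed signal of its own channel (r of 0.998 or higher), and all 6 columns had the same median, 7.04, as after quantile normalization by the authors. Which normalization the authors ran is not given in the sources used here and stays unknown. Every array's scanner file was deposited identically under both of its samples, so it was read once. The conditioned medium samples were labelled with Cy5 and the butyrate samples with Cy3 on every array, with no dye swap, and every ratio here is butyrate over conditioned medium. Arrays 1 and 2 were on slide 1 and array 3 on slide 2.

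Mean signals were background-corrected against the local background median by normexp with an offset of 50, and each array's log ratios were normalized by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3 with the data.table package, version 1.17.8. Control spots and outlier spots (5, 8 and 4 on arrays 1, 2 and 3) were left out, and spots of 1 probe were averaged. Of 41000 probes (43376 spots), 31409 were well above background on at least 2 arrays in at least 1 group and were kept. Names came through the RefSeq accession for 23680 probes, a current symbol for 2802 and a synonym for 1128, and 13390 kept the name of the array's design. The kept probe with the highest mean intensity stood for a gene, which gave 23070 genes or transcripts, 15333 under a current symbol and 7737 under the file's name. No called gene was below background on all arrays of a group, but 15 uncalled entries of 7 lists were, and their ratios are bounds only. With these genes at their bound the endoderm median is -0.70 in place of -0.71 and the WNT median -0.17 in place of -0.18, and the medians of the other 5 lists are unchanged to 2 decimals. Chromosomes were taken from the GRCh38.p14 RefSeq gene table. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 under Python 3.11.15.

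The log2 ratios of the 3 arrays were tested against 0 with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 (residual df 2, prior df 2.39). Adjusted p values of genes are from limma throughout. The labels call the samples independent, and how far the cultures were separate is not given in the sources used here, so p values measure the spread between these samples. The 40 gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, a rotation test beside it. The 23 chromosomes were tested with camera. Across genes, the ratios correlated at 0.881 between arrays 1 and 2, 0.537 between 1 and 3 and 0.647 between 2 and 3; genes are not independent replicates. Same-numbered samples shared an array, and their deviations from the group means correlated at 0.187, 0.312 and 0.329, so the ratio within an array served as the replicate block. Without the replicate block, a separate-channel fit of the 6 samples called 4511 genes.

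The tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named the 10 largest rises and 10 largest falls among called genes with a symbol and 1 sign on the 3 arrays. It also named up to 4 called members per list with the largest change, or the 2 brightest where none passed, and always a few fixed genes, among them POU5F1, SOX2, NANOG and CDKN1A. Some genes the rule picked are not reported here. In the report, CGA, TBXT, NODAL, INHBA, PAX6, COL1A1, CLDN3, SNAI1, H19 and MAGEL2 were named outside the rule and chosen after their values were seen. Genes of the Y chromosome and XIST are not reported. Alternatives were an offset of 0, no background correction, the processed signals, median centring, scale normalization, no filter, a filter on all arrays in both groups, outlier spots kept, the mean of a gene's probes, slide as a block, no replicate block or a random one, a trended robust prior, a minimum fold of 1.5, the deposited values, and each array left out. The trophoblast list without CSH1 was added after the data were seen.

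The fit was tested on simulated data of 23070 genes and 3 arrays, of which 200 genes were changed. It recovered 7.58% of 66 genes changed by a log2 of 0.5, 49.3% of 67 changed by 1 and 83.6% of 67 changed by 2, with 1 of 95 calls among unchanged genes. The simulated change was the same on all 3 arrays. In the data far more genes were called (2748), and array 3 had smaller ratios. The shares recovered in the data can therefore differ from these. Camera called the 1 list shifted in the simulation and 0 of 39 others, but with an estimated correlation it did not call the shifted list. The simulated genes varied independently of each other. In the data, the estimated correlations of the 6 lists called by camera ran from -0.04 (metallothionein list) to 0.64 (trophoblast list). The simulation therefore does not show how often lists are called falsely where genes vary together.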

Results

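BG02, an established line of human embryonic stem cells, was grown on Matrigel under 2 regimes and profiled on 2-colour Agilent gene expression arrays. The conditioned medium group was kept for 31 passages in medium conditioned by feeder cells. The butyrate group had 29 such passages, followed by 20 in medium with sodium butyrate at 0.2 mM, with neither conditioned medium nor added bFGF (FGF2). Butyrate is a short-chain fatty acid that inhibits histone deacetylases, and bFGF is the growth factor usually supplied to human embryonic stem cells. The labels describe 3 independent samples per group. Each of the 3 arrays held 1 conditioned medium sample labelled with Cy5 and the butyrate sample of the same replicate number labelled with Cy3. Median spot signals were 209, 194 and 94.9 in conditioned medium and 129, 151 and 124 in butyrate on arrays 1, 2 and 3. Between 68.1% and 78.7% of the spots were well above background in conditioned medium, the lowest share on array 3, and between 74.5% and 77.9% in butyrate. No spot was saturated. Control transcripts added at known ratios gave slopes of observed on expected log ratio of 0.92, 0.91 and 0.88 on the 3 arrays. These slopes are those of the scanner software's own ratios, which were slightly compressed. No such slope was computed for the ratios used here, which can be more compressed. Their median over the endoderm list was -0.71, against -1.17 with an offset of 0 and -2.39 with the software's processed signals. With 3 arrays, their number limits the precision.

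The comparison asks how the transcriptome of cells maintained in butyrate differed from that of cells maintained in conditioned medium. Butyrate-grown cells held far more RNA of the pluripotency-associated gene DPPA5 and of BST2, CTSF and KLK8. They held far less RNA of the muscle myosin light chains MYL4 and MYL7, of the actin ACTA1 and of the endoderm genes CXCR4 and SOX17. Of 23070 genes or transcripts tested, 1421 were higher in butyrate and 1327 were lower by limma at a Benjamini-Hochberg adjusted p threshold of 0.05. At least 2-fold changes were found for 218 of the higher and 140 of the lower genes. Of 1363 other probes kept for called genes, 1161 had the same sign, and of the 127 for genes changed at least 2-fold, 120. Arrays 1 and 2 shared a slide. With slide as a block 7606 genes passed, and within that slide (without array 3) 8182. Both counts rest on the spread between arrays 1 and 2 alone and leave out the spread to array 3. The other slide held 1 array, which gives no test. With limma no gene passed without array 1 or without array 2 (5108 and 3449 at an unadjusted p under 0.05) or after scale normalization between arrays (6569), and median centring in place of loess left 103 genes, 71 higher and 32 lower. Because no array had the dyes swapped, a gene's dye effect and its difference between groups cannot be told apart, and the contrast combines butyrate, the medium, bFGF and passage history.

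The largest rise was that of DPPA5, with a log2 ratio of butyrate over conditioned medium of 4.70 ± 0.66 (SD, n = 3), a 25.9-fold difference with a limma adjusted p of 0.0107. TBX1, a T-box transcription factor of pharyngeal development, followed at 4.04 ± 1.17. BST2, the interferon-inducible tetherin, stood at 3.53 ± 0.45, and VAV1, a guanine nucleotide exchange factor of blood cells, at 2.93 ± 1.15. The lysosomal protease CTSF (2.79 ± 0.53), the kallikrein KLK8 (2.78 ± 0.21), the TNF family ligand CD70 (2.64 ± 0.73), the pentraxin NPTX2 (2.56 ± 0.53) and the calcineurin-like CHP2 (2.39 ± 0.13) were also among the 10 largest rises. The largest falls were those of the atrial myosin light chains MYL4 (-3.41 ± 0.33) and MYL7 (-3.24 ± 0.22) and of the skeletal muscle actin ACTA1 (-3.21 ± 0.29), the first of them 10.6-fold; probes of the near-identical actin genes ACTA1, ACTA2 and ACTC1 can share signal. The transcription factor SP5 (-2.74 ± 0.39), the natriuretic peptide NPPB (-2.66 ± 0.43), the receptor tyrosine kinase ERBB4 (-2.61 ± 1.21) and SPATS2L (-2.39 ± 0.08) came next, followed by CXCR4 (-2.34 ± 0.39), SOX17 (-2.33 ± 0.70) and GSC (-2.24 ± 0.52). Adjusted p values of the genes named here lay between 0.00612 (SPATS2L) and 0.0417 (ERBB4). A dimmer probe showed the same sign but a far smaller change for TBX1 (0.29), MYL4 (-1.06), ERBB4 (-0.43), SOX17 (-0.16) and GSC (-0.84), and for SP5 at 1 of its 2 other probes (-0.28).

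**Figure D1:**
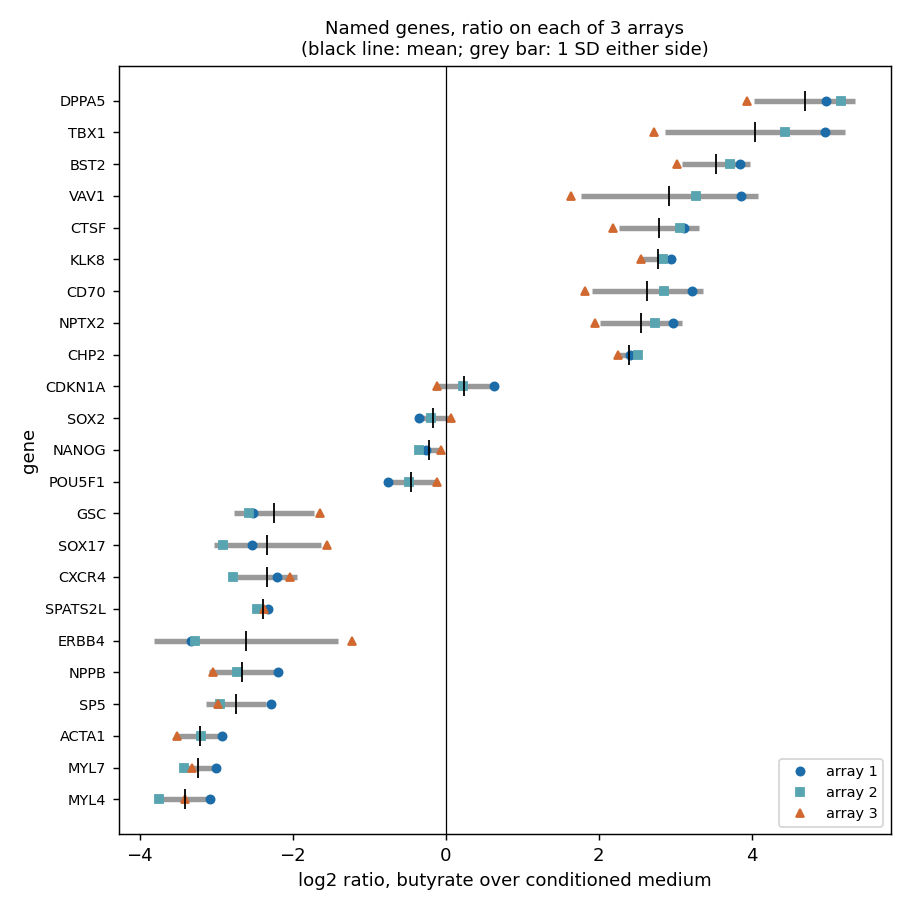
Log2 ratio of butyrate over conditioned medium (x axis) for the named genes among the 10 largest rises and 10 largest falls and for 4 genes fixed in advance (y axis), with points for the 3 arrays, a black line for the mean and a grey bar for 1 SD either side. DPPA5 reaches 4.70 and MYL4 lies at -3.41, while POU5F1, SOX2, NANOG and CDKN1A lie within 0.45 of 0.

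The core pluripotency factors did not pass the test. POU5F1 (OCT4) had a log2 ratio of -0.45 ± 0.32 (SD, n = 3, limma adjusted p = 0.0995), SOX2 -0.16 ± 0.21 and NANOG -0.22 ± 0.15. The POU5F1 value is uncertain, because its 3 other probes gave ratios of 0.23 to 0.57 and the gene has near-identical retrocopies; the mean of its probes was 0.16. In slide-blocked values POU5F1 was at -0.36 (adjusted p = 0.0211), and without array 3 it was at -0.61 (adjusted p = 0.00734), SOX2 at -0.27 (0.0393) and NANOG at -0.31 (0.0214). These limma p values rest on the spread between arrays 1 and 2 alone, which shared a slide. They leave out the spread to array 3. Of the 23 measured core pluripotency genes, 6 rose, 2 fell and 15 did not pass, against 9 and 3 adjusted over the list alone. DNMT3B, the de novo DNA methyltransferase of these cells, rose by 0.83 ± 0.28, DPPA2 by 0.79 ± 0.13 and DPPA4 by 0.60 ± 0.23, while the neuropeptide gene GAL fell by 1.40. The list as a whole did not pass (camera adjusted p = 0.0937). Among 19 naive or inner cell mass genes, DPPA5 and the germ-cell alkaline phosphatase ALPG (1.84) rose, KLF5 fell (-0.74) and 16 did not pass, against 3 and 1 adjusted over the list alone. Of 15 primed epiblast genes 2 rose, 4 fell and 9 did not pass, against 4 and 7 adjusted over the list alone; the N-cadherin gene CDH2 (-1.23), the secreted WNT modulator SFRP2 (-1.22) and the ERK phosphatase gene DUSP6 (-0.53) fell and the surface marker CD24 (0.69) rose.

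Several genes of the first steps of endoderm and mesendoderm formation were lower in butyrate. Of 20 measured endoderm genes 9 fell, 1 rose and 10 did not pass, against 14 and 1 adjusted over the list alone. CXCR4 and SOX17, both markers of definitive endoderm, fell (log2 ratios -2.34 and -2.33), as did the apolipoprotein APOA1 (-2.24 ± 0.48) and the thyroxine carrier TTR (-2.14 ± 0.72), whereas the tight junction gene CLDN6 rose by 1.03. Of 12 primitive streak and mesendoderm genes 6 fell, none rose and 6 did not pass, against 9 falling adjusted over the list alone. GSC, a homeobox gene of the organizer (-2.24), FOXA2, which is on both lists (-2.09 ± 1.06), WNT3 (-1.71 ± 0.28) and the secreted antagonist CER1 (-1.33) fell, while TBXT (brachyury) was at -0.11 and did not pass. With camera, both lists were shifted down, the endoderm list with a median log2 ratio of -0.71 (adjusted p = 1.01e-05) and the primitive streak list with a median of -0.52 (adjusted p = 0.000275). Neither call held when the correlation among genes was estimated from the 3 arrays (adjusted p = 0.779 with an estimated correlation, for both). That version of camera also missed the shifted list of the simulation, so a list that fails it may still be shifted. The endoderm median was -0.91 and -0.93 on the arrays of the first slide and -0.39 on the other, and -0.60 with slide as a block. That of the primitive streak list was -0.63, -0.70 and -0.44 on arrays 1, 2 and 3, and -0.48 with the block. Both sizes depended on the processing: with the scanner software's processed signals the endoderm median was -2.39 and the primitive streak median -1.03, and over all settings they lay between -2.39 and -0.49 and between -1.04 and -0.38.

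Among targets of activin and nodal signalling, several feedback genes were lower in butyrate. Of 17 measured, 8 fell, 3 rose and 6 did not pass, against 8 and 4 adjusted over the list alone. The feedback antagonists LEFTY2 and LEFTY1 (-1.69 ± 0.11 and -1.46 ± 0.12), the activin-binding protein gene FST (-1.80 ± 0.24) and NODAL itself (-0.65) fell, while INHBA, which encodes an activin subunit, rose by 0.88. The list missed the threshold (camera adjusted p = 0.0580), but passed under 9 of 19 alternative settings (lowest adjusted p = 0.00807).

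**Figure D2:**
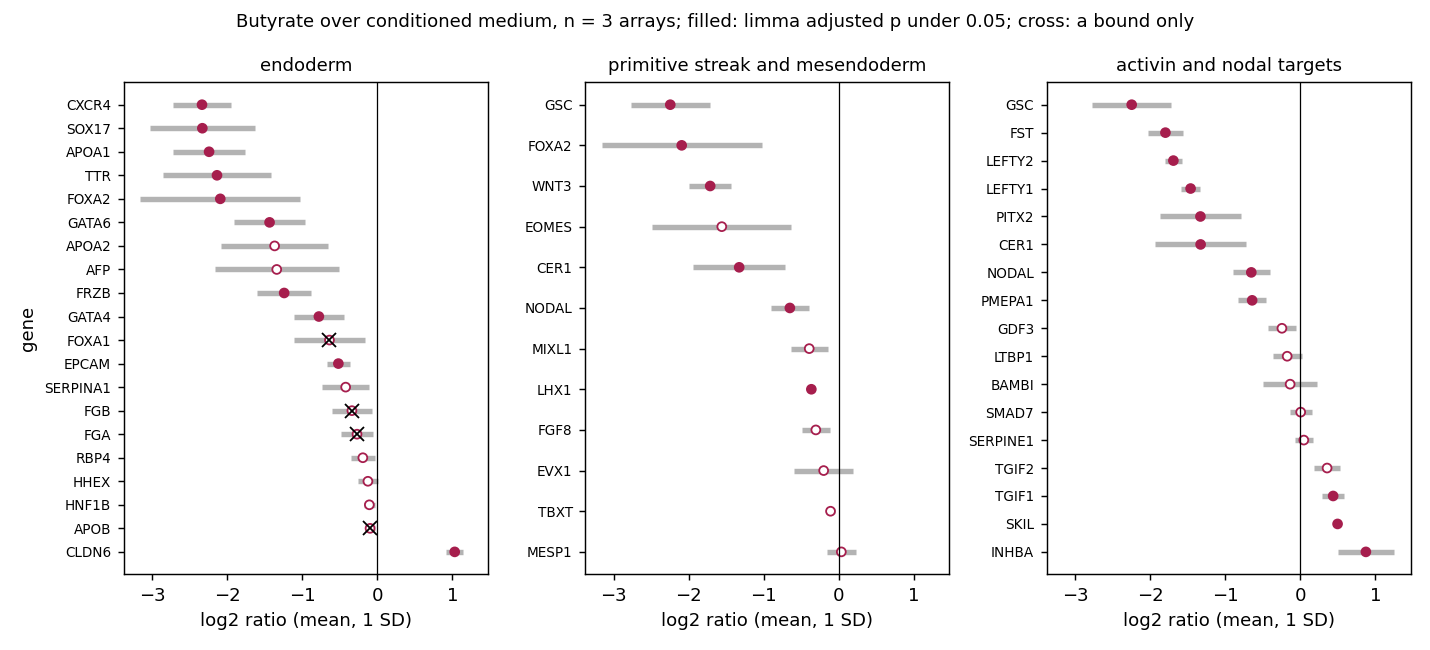
Log2 ratio of butyrate over conditioned medium (x axis) for each measured gene (y axis) of the endoderm, primitive streak and activin or nodal lists, as the mean of 3 arrays with a bar for 1 SD either side, filled points for limma adjusted p under 0.05 and crosses for genes not well above background on any butyrate array, whose ratio is a bound. Falls of over 2 on the log2 scale are those of CXCR4, SOX17, APOA1, TTR, FOXA2 and GSC, and CLDN6 and INHBA lie to the right of 0.

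The lists of mesoderm, ectoderm and their derivatives did not pass (camera adjusted p of 0.163 or higher). Of 19 mesoderm genes 5 fell, 1 rose and 13 did not pass, against 6 and 2 adjusted over the list alone; the cardiac actin ACTC1 (-2.13 ± 0.45), HAND1 (-1.07) and PDGFRB (-0.86) fell, and the VEGF receptor KDR rose by 1.18 ± 0.05. FABP7, a fatty acid binding protein of neural progenitors, rose by 1.38 ± 0.06 and was the 1 gene of 19 on the neural ectoderm list to pass, also adjusted over the list alone; PAX6 was at -0.17. None of 16 neural crest and placode genes passed, also adjusted over the list alone; its 2 brightest genes, SNAI2 and FOXD1, were at -0.47 and 0.23. Of 18 surface epithelium genes LAMB3 rose (0.64), EPCAM fell (-0.52) and 16 did not pass, against 1 and 2 adjusted over the list alone. Of 15 endothelium and blood genes CLDN5 rose (0.79), TEK fell (-0.69) and 13 did not pass, with the same counts adjusted over the list alone. In the fibroblast and stroma list, which marks cells that could arise by differentiation, S100A4 rose (1.46), ACTA2 (-1.96), TAGLN (-1.13) and CCN2 (-0.62) fell and 16 of 20 did not pass, against 2 and 4 adjusted over the list alone; the collagen gene COL1A1 was at 0.75 ± 0.60 and did not pass.

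The trophoblast list was shifted up by camera with the preset correlation, but not with an estimated one. CSH1, which encodes placental lactogen, rose by 2.05 ± 0.24 and was the 1 trophoblast gene of 21 to pass, also adjusted over the list alone. The glycoprotein hormone subunit CGA stood at 1.88 ± 1.17 and did not pass (limma adjusted p = 0.0693). The list's median was 0.38 (camera adjusted p = 0.0107; adjusted p = 0.779 with an estimated correlation), and it was 0.78, 0.35 and 0.07 on arrays 1, 2 and 3 and 0.30 with slide as a block. Without array 1 it was 0.21 (adjusted p = 0.0262), and with the processed signals 1.16. CSH1 probes can take signal from the near-identical neighbouring genes of the same cluster. Of 18 germline and cancer testis genes TEX15 rose (0.75) and 17 did not pass, with none adjusted over the list alone; the list missed the threshold (camera adjusted p = 0.0580), but passed under 10 of 19 alternative settings (lowest adjusted p = 0.000112).

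Known targets of histone deacetylase inhibitors did not pass as a list. The cell cycle inhibitor CDKN1A, a widely used marker of such inhibitors, was at 0.25 ± 0.38 (SD, n = 3, limma adjusted p = 0.329). Of 23 genes on that list 1 rose, 6 fell and 16 did not pass, against 5 and 9 adjusted over the list alone. DHRS2, a short-chain dehydrogenase, rose by 1.26 ± 0.40, and TYMS (-1.01 ± 0.06), MT2A (-0.69) and CCN2 fell; the list did not pass (camera adjusted p = 0.30). Of 24 histone deacetylases, sirtuins and their partners 4 rose, 2 fell and 18 did not pass, against 5 and 3 adjusted over the list alone. HDAC1 rose by 0.73 ± 0.03, SIRT1 by 0.91 ± 0.06 and HDAC5 by 0.58, whose other probes disagreed in sign (-0.20 and 0.71), while HDAC7 fell by 0.54. Among 16 histone acetyltransferases and readers BRD3 (-0.34) and KAT6A (-0.32) fell and 14 did not pass, with the same counts adjusted over the list alone. Of 19 genes of DNA methylation and polycomb complexes 3 rose, 2 fell and 14 did not pass, against 4 and 2 adjusted over the list alone; CBX7 rose by 1.03 and DNMT3B by 0.83, and BMI1 fell by 0.64. Of 19 clustered histone genes and variants H2AZ1 (-0.87), H2BC12 (-0.47) and H2BC9 (-0.31) fell and 16 did not pass, against 6 falling and 1 rising adjusted over the list alone; near-identical histone genes can share probe signal. Of 25 imprinted genes KCNQ1 rose (0.59), GRB10 (-0.72), NDN (-0.51), GNAS (-0.45) and MAGEL2 (-0.43) fell and 20 did not pass, against 1 and 6 adjusted over the list alone; the other probes of GNAS ranged from -0.62 to 0.31. H19 was at -0.73 ± 0.44 and did not pass.

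Signalling target genes were mixed, although the butyrate cultures had no added bFGF. Of 23 FGF and ERK targets 2 rose, 4 fell and 17 did not pass, against 3 and 4 adjusted over the list alone. The immediate early gene EGR1 rose by 1.78 ± 0.76, the ERK phosphatase genes DUSP4 (-0.54) and DUSP6 (-0.53) and the early response gene IER3 (-0.75) fell. Of 15 FGF ligands and receptors 2 rose, 2 fell and 11 did not pass, against 3 and 6 adjusted over the list alone; FGF2 itself rose by 0.43, FGFRL1 by 0.43, and FGF13 (-1.27 ± 0.09) and FGF1 (-0.75) fell. Of 17 BMP targets ID2 (-0.96) and MSX1 (-0.49) fell and 15 did not pass, with the same counts adjusted over the list alone. Of 20 WNT targets 3 fell, 2 rose and 15 did not pass, against 6 and 2 adjusted over the list alone. SP5 (-2.74) and WNT3, a ligand on that list (-1.71), fell, while AXIN2 (0.58), a feedback gene of the pathway whose 2 other probes disagreed in sign (-0.04 and 0.42), and TCF7 (0.53) rose. The WNT list was shifted down with a median of -0.18 (camera adjusted p = 0.0459; adjusted p = 0.779 with an estimated correlation), a call lost without array 3 (median -0.20, adjusted p = 0.0868). Its median was -0.17, -0.17 and -0.12 on arrays 1, 2 and 3 and -0.21 with slide as a block, and it reached -0.56 with the deposited value table.

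Most proliferation genes did not pass the test. Of 30 cell cycle genes 3 rose, 2 fell and 25 did not pass, against 7 and 3 adjusted over the list alone; the replication licensing genes CDC6 (0.51) and MCM2 (0.48) rose, and TYMS (-1.01) and KIF20A (-0.53) fell. Of 16 cyclin-dependent kinase inhibitors, D cyclins and partners CCND2 (-0.86) and CDK6 (-0.63) fell and 14 did not pass, with the same counts adjusted over the list alone. Of 20 p53 targets 2 rose, 2 fell and 16 did not pass, against 3 and 4 adjusted over the list alone; the stress cytokine GDF15 rose by 1.31 ± 0.37 and TP53I3 fell by 1.24 ± 0.02. Of 20 apoptosis regulators CASP9 (0.85) and BCL2L11 (0.33) rose, 2 genes including BID (-0.36) fell and 16 did not pass, against 5 and 3 adjusted over the list alone.

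Metallothionein and oxidative stress genes were lower as a list. Of 21 metallothionein and oxidative stress genes 7 fell, 1 rose and 13 did not pass, against 9 and 1 adjusted over the list alone. The metal-binding genes MT1F (-1.06 ± 0.03), MT2A (-0.69) and MT1M (-0.51) fell, whereas the haem oxygenase gene HMOX1 rose by 0.95 ± 0.05. The list was shifted down with a median of -0.18 (camera adjusted p = 0.00165; adjusted p = 0.779 with an estimated correlation), and it was the 1 list of 40 to pass fry, a rotation test of its own genes (adjusted p = 0.0217). Its median was -0.26, -0.20 and -0.12 on arrays 1, 2 and 3, -0.22 with slide as a block and -0.44 with median centring in place of loess, and metallothionein probes can share signal among near-identical genes. Of 15 heat shock genes 4 fell, 1 rose and 10 did not pass, with the same counts adjusted over the list alone; DNAJA1 (-0.66), BAG3 (-0.57) and HSPA1A (-0.49) fell, the last against its 2 other probes (0.06 and 0.31), and HSPA4 rose (0.45). Of 20 genes of the unfolded protein and amino acid stress responses ATF3 (-0.81) and the asparagine synthetase gene ASNS (-0.86, against 0.08 at its other probe) fell and 18 did not pass, with the same counts adjusted over the list alone.

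Several genes of fatty acid and short-chain acid handling were higher in butyrate. Of 23 such genes 4 rose, none fell and 19 did not pass, against 6 rising adjusted over the list alone. The mitochondrial acetyl-CoA synthetase gene ACSS1 rose by 1.40 ± 0.43, SLC16A1, whose product MCT1 carries monocarboxylates including butyrate, by 1.14 ± 0.23, and the carnitine palmitoyltransferase gene CPT2 by 0.49; the list did not pass (camera adjusted p = 0.0725). Of 14 fatty acid synthesis genes 4 rose, 1 fell and 9 did not pass, against 7 and 4 adjusted over the list alone; the lipogenic regulator SREBF1 rose by 1.31 ± 0.12, ELOVL5 by 0.58 and ACSL1 by 0.57. Of 22 cholesterol synthesis genes 3 rose, including PMVK (0.36), MVK fell (-0.61) and 18 did not pass, against 5 and 5 adjusted over the list alone. Of 24 oxidative phosphorylation genes COX7B (0.42), COX7A2 (0.34) and CYC1 (0.30) rose, none fell and 21 did not pass, against 5 rising adjusted over the list alone (camera adjusted p = 0.0816 for the list). Of 25 glycolysis and hypoxia genes ENO2 (1.12) and PKM (0.48) rose, ADM fell (-0.76) and 22 did not pass, against 4 and 3 adjusted over the list alone.

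Cell adhesion genes changed in both directions. Of 17 genes of cell junctions and mesenchymal transition 5 rose, 3 fell and 9 did not pass, against 7 and 7 adjusted over the list alone. The E-cadherin gene CDH1 rose by 1.02 ± 0.26, CLDN6 by 1.03 and CLDN3 by 0.90, and CDH2 (-1.23 ± 0.24) and the mesenchymal intermediate filament gene VIM (-1.41 ± 0.23) fell; EPCAM fell too (-0.52) and the transition factor SNAI1 rose (0.34). Of 23 extracellular matrix and integrin genes none rose and 20 did not pass, with the same counts adjusted over the list alone; the osteopontin gene SPP1 (-1.72 ± 0.25), LAMB1 (-0.95) and ITGB5 (-0.91) fell.

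Some interferon-response and antigen presentation genes rose. Of 22 measured 4 rose, none fell and 18 did not pass, against 8 rising adjusted over the list alone. IFIT1 rose by 1.21 ± 0.21, B2M, the light chain of class I molecules, by 1.02 ± 0.10, the immunoproteasome subunit PSMB9 by 0.88 ± 0.12 and ISG15 by 0.30. The list was shifted up with a median of 0.17 (camera adjusted p = 0.0138; adjusted p = 0.779 with an estimated correlation); the median was 0.27, 0.19 and 0.04 on arrays 1, 2 and 3 and 0.12 with slide as a block. It was 0.08 without array 1 (adjusted p = 0.0216) and 0.07 with median centring. Of 27 housekeeping genes 3 rose, 4 fell and 20 did not pass, against 6 and 6 adjusted over the list alone. TFRC (1.11), B2M and CHMP2A (0.47) rose, and ACTB (-0.82) fell. Across the 40 lists, 2 were shifted up and 4 down by camera with a preset correlation of 0.01. None was with an estimated correlation, where all adjusted p were 0.779 or higher. Even the metallothionein list, whose estimated correlation (-0.04) lay below the preset one, was at 0.779. With 3 arrays this version therefore does not tell shifted lists from others. Of the 34 lists that did not pass, 15 passed under at least 1 alternative setting, none but the germline and the activin and nodal lists under more than 4. Median and mean differed in sign for the naive, FGF and ERK, apoptosis, cholesterol and extracellular matrix lists, none of which passed. Of 52 called genes named by the rule that had another kept probe, 30 had 1 at under 50% of the change or of opposite sign. Among list genes, a probe of the same sign showed a far smaller change for ALPG (0.19), ACSS1 (0.34), FGFRL1 (0.00), CLDN5 (0.22), MVK (-0.07), BRD3 (-0.08), ATF3 (-0.25), BCL2L11 (0.04), FOXA2 (-0.34), FGF1 (-0.03), DNAJA1 (-0.16) and CSH1 (0.40), the last 5 of which had further probes.

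**Figure D3:**
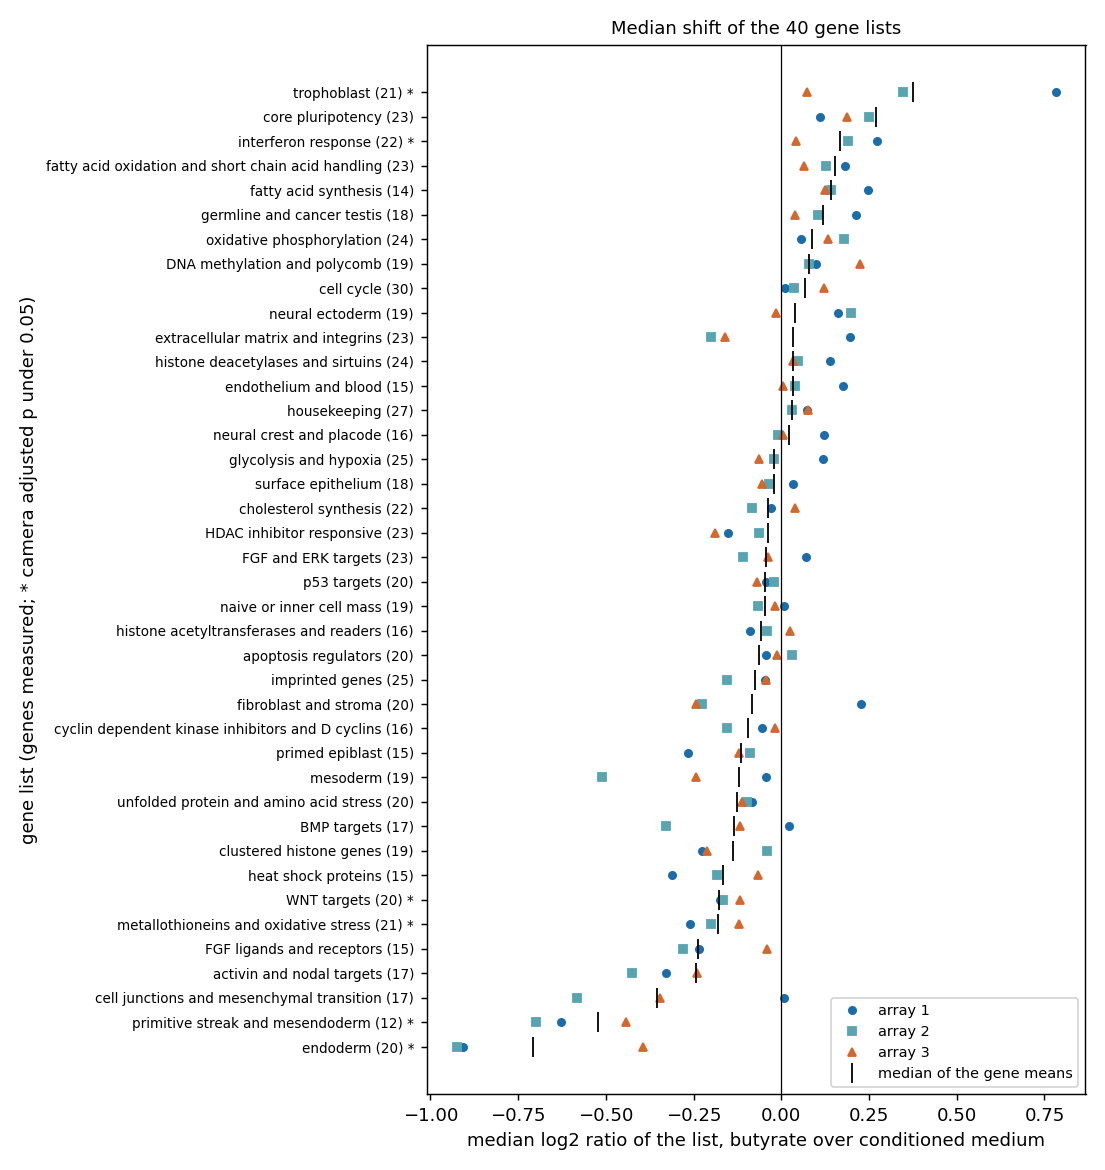
Median log2 ratio of butyrate over conditioned medium (x axis) of each of 40 gene lists (y axis, with the number of genes measured), as points for the 3 arrays and a black line for the median of the gene means; an asterisk marks camera adjusted p under 0.05. The endoderm list has the lowest median (-0.71) and the trophoblast list the highest (0.38), and for both the point of array 3 lies nearest to 0.

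Genes of chromosome 19 were higher in butyrate as a group. Of its 1119 tested genes, placed by the GRCh38.p14 RefSeq annotation, 165 were higher and 22 lower, and their median log2 ratio was 0.13 (camera adjusted p = 4.85e-08; adjusted p = 0.959 with an estimated correlation). BST2, VAV1, KLK8 and CD70 lie on this chromosome. The median was 0.21 and 0.16 on the arrays of the first slide and 0.04 on the other, and 0.10 with slide as a block; it ranged from 0.06 with median centring to 0.23 with the deposited value table. None of the other 22 chromosomes tested was shifted; the nearest was chromosome 18, with a median of -0.07 (adjusted p = 0.439), which passed only without array 3 (-0.12, adjusted p = 0.0142).

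**Figure D4:**
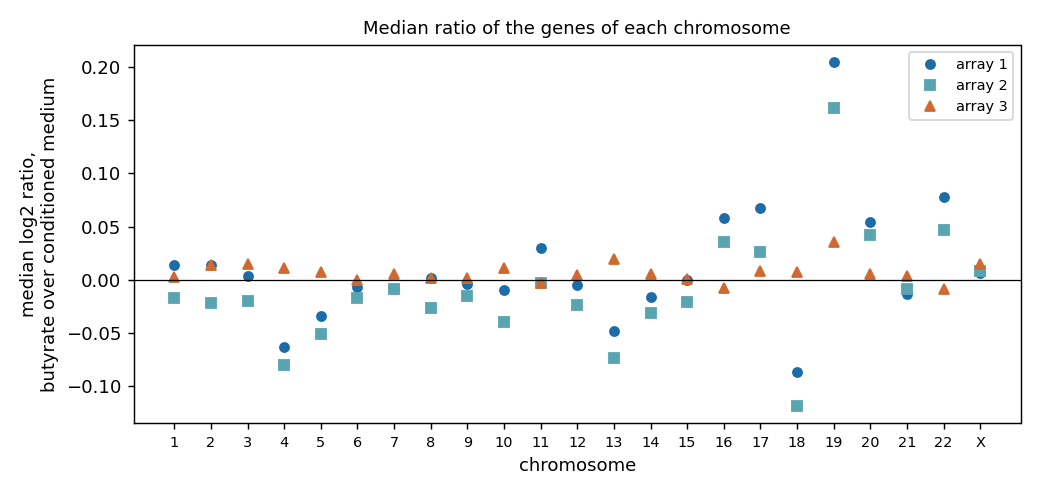
Median log2 ratio of butyrate over conditioned medium (y axis) of the genes of each chromosome (x axis), with 1 point per array. Chromosome 19 has the highest median on each array, 0.21, 0.16 and 0.04 on arrays 1, 2 and 3.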

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

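The trophoblast list without CSH1 was run after the result was seen, and kept its call (0.35, adjusted p = 0.0312); the other alternatives were planned. All 136 called genes among the 143 named by the rule kept their direction under every setting, as did 29 genes named later. For many settings this was fixed in advance, since all 2748 called genes had 1 sign on the 3 arrays. Leaving out an array, changing the block or prior, scale normalization and the minimum fold could not turn such a sign. How many of the 136 passed ranged from 0 (scale normalization, or without array 1 or 2) to 136. POU5F1, not called, turned to 0.16 with the mean of its probes, which differ in sign. The count of 2748 genes became 6246 with no background correction, 5041 with processed signals, 5022 with the deposited table, 7606 with slide as a block, 4511 with no replicate block, 5405 with the replicate block as a random effect, 50 against a minimum fold of 1.5 and 103 with median centring, where 68.9% of calls were higher against 51.7%. Scale normalization left 0 (limma, 6569 at an unadjusted p under 0.05), and leaving out an array gave 0 to 8182. A minimum fold is stricter by construction. With slide as a block or without array 3, the spread is only that between arrays 1 and 2 of 1 slide. Otherwise the cause was not tested. The 6 shifted lists became 13 with median centring, 11 with no filter, 11 with the mean of probes, 0 with an estimated correlation, 1 with fry and 7 to 13 with an array left out. The 1 shifted chromosome became 0 with an estimated correlation and 1 to 2 with an array left out. The WNT list also lost its call, though its median was no smaller, under scale normalization (-0.23, adjusted p = 0.0636), the strict filter (-0.26, 0.0867) and the trended prior (-0.18, 0.0964); over its settings adjusted p ranged from 0.00747 to 0.779.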

Other observations

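The genes named here but not in the report, the patterns weighed, and the tests of an extra chromosome copy, base composition, compressed ratios and differentiated cells, were chosen after the result was seen. Every SE below was taken over genes of the same 3 arrays, and genes are not independent replicates. The spread between arrays is not in these SEs. Probes of other genes of the placental growth hormone cluster gave values like that of CSH1: CSH2 had a log2 ratio of 2.08 ± 0.59 (SD, n = 3, limma adjusted p = 0.0212), CSHL1 2.10 ± 0.67 and the pituitary hormone gene GH1 2.06 ± 0.69. These near-identical genes can share probe signal, so it is unknown which of them changed. Beyond the fixed interferon list, the antiviral GTPase gene MX2 rose by 2.15 ± 0.68 and DHX58, which encodes a regulator of RNA sensing, by 1.69 ± 0.22. The nonclassical class I genes HLA-F (0.74) and HLA-E (0.69) and the peptide transporter gene TAP1 (0.45) rose too.

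The actins and myosin light chains ACTA1, ACTA2, ACTC1, MYL4 and MYL7 fell with TAGLN and NPPB, and were grouped because they fell. Lower activity of SRF with its MRTF cofactors, which drive such genes, is a candidate explanation. The 24 other known targets had a median of -0.38 (camera p = 3.6e-06, 0.312 with an estimated correlation). Of these 10 fell, among them SRF (-0.75), CALD1 (-1.44), ACTG2 (-1.39), MYL9 (-1.12), CNN1 (-1.07) and TPM1 (-0.92), while FHL1 rose (0.75). The rest did not pass and ran from -0.59 (TPM2) to 0.52 (FLNA), with VCL (0.02) and ZYX (0.06) near 0. Other probes were weaker for SRF (-0.27 and -0.22) and ranged from -1.26 to -0.32 for CALD1 and, with both signs, from -1.05 to 0.49 for TPM1. Cardiac muscle cells in the conditioned medium cultures stay open. A list of 16 other cardiac genes, which also held the skeletal muscle troponin gene TNNI2 (0.02), had a median of -0.11 (SE 0.145). This lay above the bound of -0.5 set in advance. However, 4 of the 16 were not well above background on all arrays in both groups, so that a fall might not show. The other 12, set apart after the value was seen, were at -0.29 (SE 0.202), less than 2 SE from that bound. Among them TNNT2 (-0.94) and TNNC1 (-1.09) fell, NPPA was at -1.23 and TNNI3 rose (1.35). A dye bias of single probes cannot be told apart from a change, since only 3 other probes of these genes were kept, although 100% of them were negative.

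An extra copy of chromosome 19 in a share of the butyrate cells stays open. The median of 0.13 (SE over genes 0.0121) was 0.21, 0.16 and 0.04 on arrays 1, 2 and 3, and ranged from 0.06 to 0.23 over the settings. How far a copy would raise it in compressed ratios and a mix of cells is unknown. The shift was not a matter of the chromosome's zinc finger genes alone, because its 904 other genes lay 0.13 above all genes (their median was 0.13, against 0.14 for 215 zinc finger genes). Nor was it shared by equally gene-dense places elsewhere, from which it differed by 0.12 (SE over genes 0.0119). Base composition of the probes acting through the dyes cannot be told apart from a change in the cells without a dye swap: over the other 22 chromosomes the median ratio followed local gene number (Spearman's rho 0.658, permutation p = 0.0012, Pearson's r 0.739). A regional response to butyrate was not tested.

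Array 3, alone on its slide, had smaller ratios: over 672 genes changed at least 2-fold on array 1, the slope on array 1 was 0.517 for array 3 and 0.891 for array 2, which underwent the same selection of genes. Whether compression of ratios by that array accounts for it cannot be told. The spike-in slope there was 0.967 of the mean of the others, but this holds for the scanner software's own ratios. The ratios used here can be more compressed, and no such slope was computed for them on array 3. Signals near background in its dimmer red channel could account for part: among the brightest genes these slopes were 0.789 and 0.965, and the slope on the mean of arrays 1 and 2, for genes chosen on these, was 0.842 (SE 0.0212). Whether fewer endoderm, primitive streak or trophoblast cells on array 3 account for the whole cannot be told. The 650 genes outside these lists shared the loss, with slopes of 0.519 for array 3 and 0.886 for array 2, a ratio of 0.585 (SE over genes 0.0131). Such cells also express genes that are on no list, so these genes do not decide it. A further loss in the list genes, beside this shared loss, stays open too. Over genes chosen on the mean of arrays 1 and 2, the slope of 20 genes of these lists was 0.510 and that of the others 0.594, a difference of -0.0833 (SE over genes 0.0602).

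The 6 samples can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 2748 genes and the highest other 0, with 1 of 10 splits reaching the real count. It gave 6 lists against at most 11 (7 of 10 splits gave as many) and 1 chromosome against at most 6 (6 of 10). The same-numbered samples pair on arrays, and 4 splits part all pairs, the real one included. The others of these mix the dyes within a group, and they gave at most 0 genes, 11 lists and 6 chromosomes. In every split but the real one, a difference shared by the arrays counts as spread, which works against gene calls. The 0 genes are therefore no reference for the real count.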
